A study of Homo sapiens with 4 samples.

How the data were processed

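RNA of irradiated HCT116-Clone2 cells and of unirradiated HCT116-Clone10 cells was hybridised together on 4 two-colour cDNA arrays of human clones. Clone2 was in Cy5 on replicates 1 and 2 and in Cy3 on replicates 3 and 4, per the labels. Per the labels' protocols, RNA from different batches was pooled and the experiment was repeated 4 times. Whether a single pool or several were hybridised is not given in the sources used here, so p-values measure only the spread between these arrays, which may be technical.

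The deposited values are log2 ratios of the channels of an array. Per the labels' protocols, the slides were scanned with ScanArray Express and quantified with QuantArray 3.0, and an Excel macro named Normaliser2 subtracted the sub-array background, normalised each sub-array by regression on log intensity and took the log2 ratio. The same protocols describe marking of spots with a signal under 2.5 times the sub-array background, of spots under 5% of spot intensity and of damaged spots, with their removal. The table used here has 0 missing cells, so values of any spots so marked are probably still among those tested. The marks themselves were not examined, and weak spots may carry extreme ratios. The numerator, the averaging of repeated spots and any turning of the dye-swapped arrays are not given in the sources used here. Regression within sub-arrays can remove a shift shared by most genes. It left the spread of the arrays unequal and did not bring all sub-array medians to 0, with -0.48 at row 9, column 1 of replicate 4. Spot intensities were not used here, and the number of arrays limits the precision.

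The table holds 19200 spots in 48 sub-arrays of 400, laid out in 12 rows and 4 columns. Gene symbols came from the platform annotation: 10914 spots had 1 symbol, 1435 had several and 6851 had none, and no gene was named from a spot with several. Of the spots with 1 symbol, 10882 matched the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and the symbols covered 7498 genes. Spots with the same sequence identifier and gene were averaged within an array, which gave 18828 clones, of which 282 had more than 1 spot and 10593 had 1 symbol. A clone here is a printed cDNA and is distinct from the cell clones.

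The tests, gene lists, rule for named genes, rule of orientation and most alternatives were fixed before the data were examined. The rule of orientation used the median Pearson correlation between arrays of opposite dye orientation. Above 0.1 no array was to be turned, below -0.1 replicates 3 and 4 were to be turned, and in between the direction was to be called unsettled with the ratios turned by the dye labels. The median was 0.0187, so replicates 3 and 4 were multiplied by -1. The direction, irradiated Clone2 over unirradiated Clone10, rests on the labels alone and is not settled. Its basis is that the labels list Clone2 as channel 2, in Cy5 on replicates 1 and 2.

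Each clone was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean coefficient and a gene-specific dye coefficient, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Clones with a mean log2 ratio of at least 1 in size and the same sign on all 4 arrays were also counted, without a test. The 24 gene lists were tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry. They comprised p53 targets, G2/M and mitosis, DNA replication, double-strand break repair, excision and mismatch repair, interferon-stimulated genes, MHC class I presentation, antioxidant genes, apoptosis regulators, NF-kB targets and immediate early genes, glycolysis and hypoxia, cholesterol biosynthesis, chaperones and unfolded protein response, oxidative phosphorylation, proteasome, cytosolic ribosomal proteins, histones, intestinal and epithelial identity, Wnt targets and stem markers, mesenchymal transition and matrix, fibroblast markers, leukocyte markers, endothelial and erythroid markers, and housekeeping controls. Since fewer than 5 clones passed, the rule named the 10 clones with 1 symbol, the largest mean ratios and the same sign on all 4 arrays, together with CDKN1A, MDM2 and GADD45A where measured. MDM2 had no clone with 1 symbol.

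The gene test was tested on simulated data with 200 of 18828 clones changed: 0% were recovered at 2-fold, 63% at 4-fold and 92% at 8-fold, with 0, 5 and 8 false calls. The simulation used the right orientation on every array and independent noise, without wide sub-arrays. These shares may therefore not hold for the real arrays, and they do not apply if the direction was wrongly turned. Alternatives varied the dye coefficient, the normalisation between arrays, the treatment of repeated spots, the moderation, a minimum fold change, the orientation and the arrays used. Leaving out or rescaling sub-arrays with a wide spread, using replicates 1 and 2 alone, and the unturned 2-fold counts and gene lists were added after the data had been seen. Tests of position and the figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.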

Results

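Gene expression was measured on 4 two-colour cDNA arrays in clones of HCT116, a human colorectal cancer cell line. The labels describe HCT116-Clone2 as resistant to X-rays and HCT116-Clone10 as responding like the parental line. Clone2 cells had received 4 Gy of X-rays 24 h before RNA collection, and Clone10 cells were unirradiated. All 4 arrays formed a single group, with Clone2 in Cy5 on 2 arrays and in Cy3 on the other 2. Ratios are given as irradiated Clone2 over unirradiated Clone10 on the log2 scale, a direction taken from the channel labels alone. The values did not settle it. Same-sign counts and counts at an unadjusted p under 0.05 leaned against it. A gene-specific dye effect could also give those counts. Cell clone and irradiation differed together, so their contributions cannot be separated in this comparison.

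The arrays differed in spread and shared little signal. The SD of the log2 ratios over all spots was 0.515, 0.734, 0.600 and 0.865 on replicates 1 to 4, and 6.10%, 14.4%, 9.07% and 14.4% of the spots lay at least 2-fold from 0. Across spots, which are not independent replicates, the Pearson correlation was 0.184 between replicates 1 and 2 and 0.132 between replicates 3 and 4 as deposited. Between arrays of opposite dye orientation it was -0.00925, 0.00672, 0.0307 and 0.0785. The Spearman correlations of the same opposite pairs were -0.00227, 0.0443, 0.0549 and 0.125. Within an orientation they were 0.214 and 0.179.

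The comparison asked which genes differ between irradiated resistant cells and unirradiated cells of ordinary response. ST6GAL1, a sialyltransferase of the Golgi, had the most even of the 10 largest ratios, with a mean log2 ratio of 2.04 ± 0.49 (SD, n = 4), or 4.11-fold, and values of 1.82, 2.40, 2.48 and 1.46 on replicates 1 to 4. ATF6, a sensor of the unfolded protein response, stood at 2.06 ± 0.84, and TNFRSF10D, a decoy receptor for the death ligand TRAIL, at 2.25 ± 1.46. CDKN1A, the cyclin-dependent kinase inhibitor induced by p53, stood at 0.17 ± 0.69, and GADD45A, a DNA-damage-inducible gene, at 0.27 ± 0.20, 0.07 ± 0.66 and 0.06 ± 0.34 on its 3 clones. None of these genes passed the test. The sizes as well as the signs rest on turning replicates 3 and 4: unturned, the mean was 0.07 for ST6GAL1, -0.28 for ATF6 and -1.25 for TNFRSF10D.

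No clone passed limma's test: 0 of 18828 had an adjusted p under 0.05, and the smallest adjusted p was 0.705. At an unadjusted p under 0.05 there were 1275 clones, of which 853 had positive and 422 negative ratios, against 941.4 expected by chance. With replicates 3 and 4 unturned there were 1704, of which 1122 were positive and 582 negative. With each array centred on its median the split was 688 positive and 557 negative. In simulated data of this size, with 200 clones changed and the orientation right, 0% of 2-fold changes were recovered. Changes of that size were therefore unlikely to be detected with these arrays. The simulation does not cover a wrongly turned direction, so the absence of calls does not exclude larger changes. The dye coefficient also gave 0 clones past the threshold in limma, with a smallest adjusted p of 0.544 and 1704 clones at an unadjusted p under 0.05. It is the same quantity as the unturned mean, hence the same 1704 clones. A dye effect and an unturned expression difference therefore cannot be told apart by it.

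The remaining 7 of the 10 largest ratios were less even over the arrays. TMEM107, a protein of the ciliary transition zone, had a mean of 2.53 ± 1.90, TENT4A, a noncanonical poly(A) polymerase, 2.42 ± 1.69, and SOX10, a neural crest transcription factor, was 4.59-fold with an SD of 1.60 on the log2 scale. TNS3, a focal adhesion protein, had a mean of 2.01 ± 1.58. DENND5A, a regulator of Rab GTPases, also had a mean of 2.01, from 1.20, 0.54, 1.68 and 4.61 on replicates 1 to 4. HNMT, the histamine methyltransferase, had 2.14 ± 3.48, and CORIN, a serine protease, 1.99 ± 3.35, and both SDs exceeded the mean. Adjusted p in limma lay between 0.705 and 0.707 for all 10 genes. ST6GAL1, TNFRSF10D, TMEM107 and TENT4A had no other clone with 1 symbol, so each rests on a single spot per array. For the remaining genes, other clones on the same arrays differed in sign or size. ATF6 had means of -0.82 ± 0.28 and -0.11 ± 0.60 on its other clones, SOX10 -0.10 ± 0.12 and CORIN -0.26 ± 0.54. HNMT had 1.01 ± 1.10 and -0.12 ± 0.87, TNS3 0.09 ± 0.30 and DENND5A 0.17 ± 0.86. All 10 clones lay in sub-arrays whose ratios spread widely on replicate 4. Unturned, the means were -0.98 for TMEM107, 0.61 for TENT4A, -0.77 for SOX10, -0.56 for TNS3, -1.14 for DENND5A, -1.86 for HNMT and -1.70 for CORIN. After each sub-array had been centred and scaled, the mean of ST6GAL1 was 1.78 and those of HNMT and CORIN were 0.57 and 0.50. TENT4A was then at 1.35, TMEM107 at 1.28, TNFRSF10D at 1.24, ATF6 at 1.08, SOX10 at 1.02, DENND5A at 0.92 and TNS3 at 0.91.

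**Figure D1:**
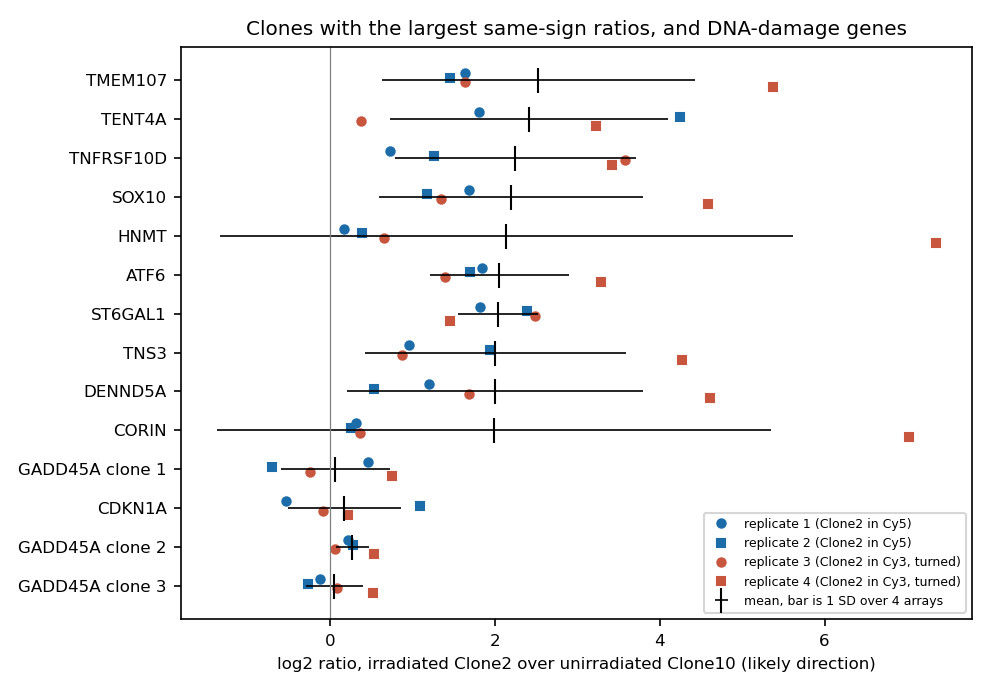
Log2 ratio (horizontal axis) of each array. Shown are the 10 clones with the largest mean ratios of the same sign on all arrays, and CDKN1A and GADD45A. Colour gives the dye orientation, blue for replicates 1 and 2 and red for replicates 3 and 4. Circles mark replicates 1 and 3, and squares replicates 2 and 4. A vertical tick marks the mean and a bar 1 SD over 4 arrays. ST6GAL1 lies between 1.46 and 2.48 on all 4 arrays, whereas HNMT reaches 7.35 and CORIN 7.02 on replicate 4 alone.

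Ratios of at least 2-fold with the same sign on all 4 arrays were mostly positive. They numbered 167 positive and 22 negative clones, and 3001 clones of any size (15.9%) had the same sign on all 4 arrays. Unturned, 3776 (20.1%) did, and independent arrays would give 12.5%, a share that the correlation within each dye orientation lifts by itself. Of the 189 clones at 2-fold, 132 (69.8%) lay in 7 sub-arrays that hold 14.5% of all clones. These 7 were picked because the SD of their ratios on replicate 4 was over 2 times the median over the sub-arrays of that array, which by itself favours large means there. Outside them were 50 positive and 7 negative clones. With replicates 3 and 4 unturned, 119 of 197 clones at 2-fold lay outside them. The rest, inside, still exceeded the 14.5% share of all clones held there. The 7 sub-arrays held 117 of the 167 positive clones, and their medians on replicate 4 were -0.48 to -0.12 as deposited, which turning makes positive. Among the 57 turned clones outside, chosen here after their values had been seen, were SLC27A4, a fatty acid transport protein, at 1.91 ± 0.71, and APC, the tumour suppressor of the Wnt pathway, at 1.47 ± 0.57. ZNF251, a zinc finger protein, stood at 1.08 ± 0.37, SRGAP3 at 1.16 ± 0.53 and NR4A3, an orphan nuclear receptor, at -1.09 ± 0.68. PPT2 had a mean of 1.96 ± 2.80 that rested on 6.17 on replicate 2. The adjusted p in limma was 0.705 for each of these 6 genes. Unturned, the means were 0.39 for SLC27A4, -0.06 for APC, -0.25 for ZNF251, 0.31 for SRGAP3, 0.36 for NR4A3 and 1.34 for PPT2. Of 21 other clones of the genes at 2-fold outside the wide sub-arrays, 9 had the same sign (42.9%).

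**Figure D2:**
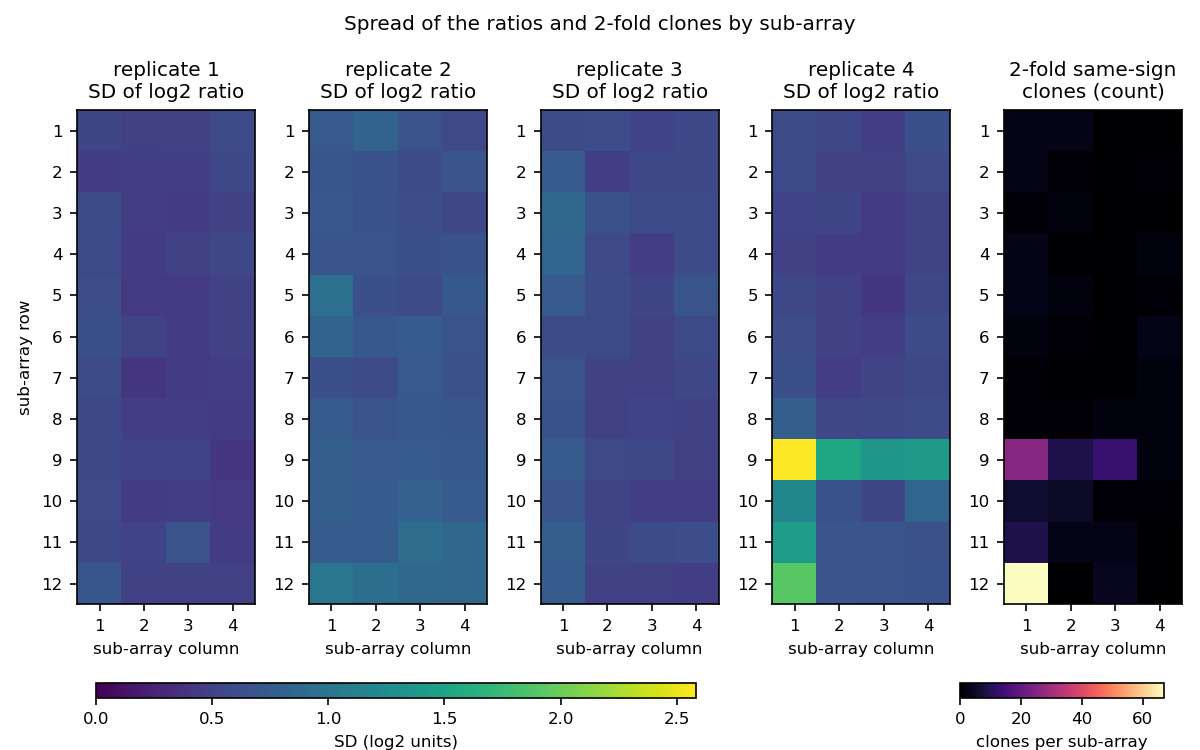
SD of the log2 ratios in each of the 48 sub-arrays (12 rows by 4 columns) on replicates 1 to 4, in log2 units, and, in the last panel, the number of clones per sub-array at least 2-fold from 0 with the same sign on all 4 arrays. The SD reaches 2.58 on replicate 4 in the sub-array of row 9 and column 1, and 132 of the 189 clones at 2-fold, with replicates 3 and 4 turned, lie in the 7 wide sub-arrays.

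Cytosolic ribosomal protein genes were the only list past the threshold of camera in limma (adjusted p = 0.0173 over 24 lists). The adjusted p was 0.623 with an estimated correlation. Their 71 clones of 40 genes had a median log2 ratio of -0.09, with 28 positive and 43 negative, against a median of 0.06 over all clones. RPL10A stood at -0.68 ± 0.29, RPL18 at -0.68 ± 0.21 and RPL35A at -0.45 ± 0.18, with RPL10A and RPL18 in a wide sub-array, and 0 members passed over all genes or adjusted over the list alone. The list median was 0.01, -0.18, -0.08 and -0.11 on replicates 1 to 4. The call was lost without replicate 2 (adjusted p = 0.30), without replicate 3 (0.130), without replicate 4 (0.0644), and with replicates 3 and 4 left unturned (0.693). It was also lost with 1 value per gene (0.0636) and with the wide sub-arrays left out (0.157). In fry, which tests the list against no change and not against other genes, the adjusted p was 0.188. Unturned, the list median was 0.01.

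Metabolic lists did not pass. Cholesterol biosynthesis genes had a median of 0.27 over 23 clones, positive on 4 of 4 arrays once turned, with 16 positive clones (camera in limma, adjusted p = 0.147). Unturned, the median was -0.06 (adjusted p = 0.657). On replicate 2 the list median of 0.08 lay below the 0.10 of all spots. Of all clones with 1 symbol outside the wide sub-arrays, 57.3% were positive once turned. The positive counts of all lists are to be read against that share. SC5D, a sterol desaturase, stood at 1.12 ± 0.33, IDI1, the isopentenyl diphosphate isomerase, at 0.83 ± 0.38, LSS, the lanosterol synthase, at 0.94 ± 0.87 and MVK, the mevalonate kinase, at -0.72 ± 0.30. SC5D and LSS lay in wide sub-arrays. Members named in the lists here were chosen by their small p after the values had been seen, and their values are turned unless stated. Glycolysis and hypoxia genes had a median of -0.13 over 37 clones, with 24 negative and the median negative on all 4 arrays once turned (adjusted p = 0.147). Unturned, the median was 0.03 (adjusted p = 0.960). GAPDH had -0.68 ± 0.15 on the clone with the smallest p and PFKL, a phosphofructokinase, -0.51 ± 0.20, whereas PFKP stood at 0.42 ± 0.39. Oxidative phosphorylation genes had a median of -0.03 over 61 clones (adjusted p = 0.392), with NDUFS1, a complex I subunit, at 0.61 ± 0.17. Antioxidant and glutathione genes had 0.02 over 78 clones (0.779), with FTL, the ferritin light chain, at 0.54 ± 0.17 and 0.68 ± 0.51 on separate clones.

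Lists of the DNA damage response and of the cell cycle did not pass. The p53 targets had a median of 0.06 over 24 clones, with 17 positive (camera in limma, adjusted p = 0.779), and a median of -0.07 unturned. Adjusted over the list alone, 1 member passed, TNFRSF10D, at 0.002 and in a wide sub-array, and 0 passed over all genes. DDB2, a damage-recognition protein, stood at 1.58 ± 1.68 in a wide sub-array. Its mean was -0.77 unturned and 0.61 with sub-arrays centred and scaled. G2/M and mitosis genes had a median of -0.07 over 28 clones (adjusted p = 0.361), with MAD2L1, a spindle checkpoint protein, at -0.67 ± 0.34 and AURKA at -0.44 ± 0.38. DNA replication genes had 0.02 over 38 clones (0.986), with TK1, the thymidine kinase, at 1.15 ± 0.84 and MCM5 at 0.73 ± 0.58. Double-strand break repair genes had 0.08 over 27 clones (0.858). RAD1, a checkpoint clamp subunit, had 0.82 ± 0.43 and 0.64 ± 0.79 on separate clones, and XRCC5 had -0.50 ± 0.45. Excision and mismatch repair genes had a median of -0.0002 and a mean of -0.02 over 27 clones (0.393), with MGMT, the methylguanine methyltransferase, at -0.57 ± 0.15. Apoptosis regulators had a median of 0.14 over 38 clones (0.490), with CASP8 at 0.95 ± 0.30 and DAPK1 at -0.67 ± 0.52. Histone genes had 0.07 over 11 clones (0.873), with array medians between -0.34 and 0.23 and a median of -0.28 unturned.

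Lists of stress, immunity and cell identity did not pass either. Chaperones and unfolded protein response genes had a median of 0.09 over 55 clones (camera in limma, adjusted p = 0.393), and HSP90B1, an endoplasmic reticulum chaperone, stood at 1.33 ± 0.76 in a wide sub-array. Interferon-stimulated genes had 0.08 over 40 clones (0.781) and MHC class I presentation genes 0.11 over 12 clones (0.781). Proteasome genes had a median of 0.004 and a mean of -0.02 over 25 clones (0.461). NF-kB targets and immediate early genes had a median of 0.0004 and a mean of 0.07 over 35 clones (0.781). NFKB2 stood at -0.71 ± 0.25 and JUNB at -0.59 ± 0.19, and, in wide sub-arrays, RELB at 1.54 ± 1.40 and DUSP5 at 1.11 ± 1.30. The unturned means were 0.12 for NFKB2, -0.007 for JUNB, -0.53 for RELB and -0.77 for DUSP5. With sub-arrays centred and scaled, RELB was at 0.64 and DUSP5 at 0.55. Intestinal and epithelial genes had a median of -0.08 over 27 clones (0.361). Wnt targets and stem markers had a median of -0.05 and a mean of 0.03 over 34 clones (0.808), with TCF7L2 at 0.69 ± 0.23 and, in a wide sub-array, MMP7 at -1.29 ± 1.05. Mesenchymal and matrix genes had a median of -0.01 and a mean of 0.03 over 73 clones (0.393), with SPARC at -0.57 ± 0.21 and TNC at 0.52 ± 0.40. Housekeeping controls had a median of -0.04 over 20 clones (0.392). Camera compares a list with all clones, whose median was 0.06, so its sign can differ from that of a list's own median. With replicates 3 and 4 unturned, 11 of the 24 lists took the other direction in camera and 0 passed.

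Markers of other cell types did not pass as lists. Fibroblast markers had a median of 0.13 over 46 clones (camera in limma, adjusted p = 0.392), with 34 positive. Adjusted over the list alone, 1 clone passed, of DCN, at 0.044 with a mean of -1.57 ± 1.15, while another clone of DCN stood at 1.02 ± 0.77, both in wide sub-arrays. With replicates 3 and 4 unturned, the means of these DCN clones were 0.94 and 0.58, and the list median was 0.13. COL3A1 stood at 0.95 ± 0.62. Leukocyte markers had a median of 0.06 over 28 clones (0.781) and endothelial and erythroid markers 0.15 over 45 clones (0.873), with PECAM1 at 1.27 ± 1.29 and KDR at -0.86 ± 0.54. In every list 0 members passed over all genes. Adjusted over the list alone, 0 passed in all lists except p53 targets and fibroblast markers.

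**Figure D3:**
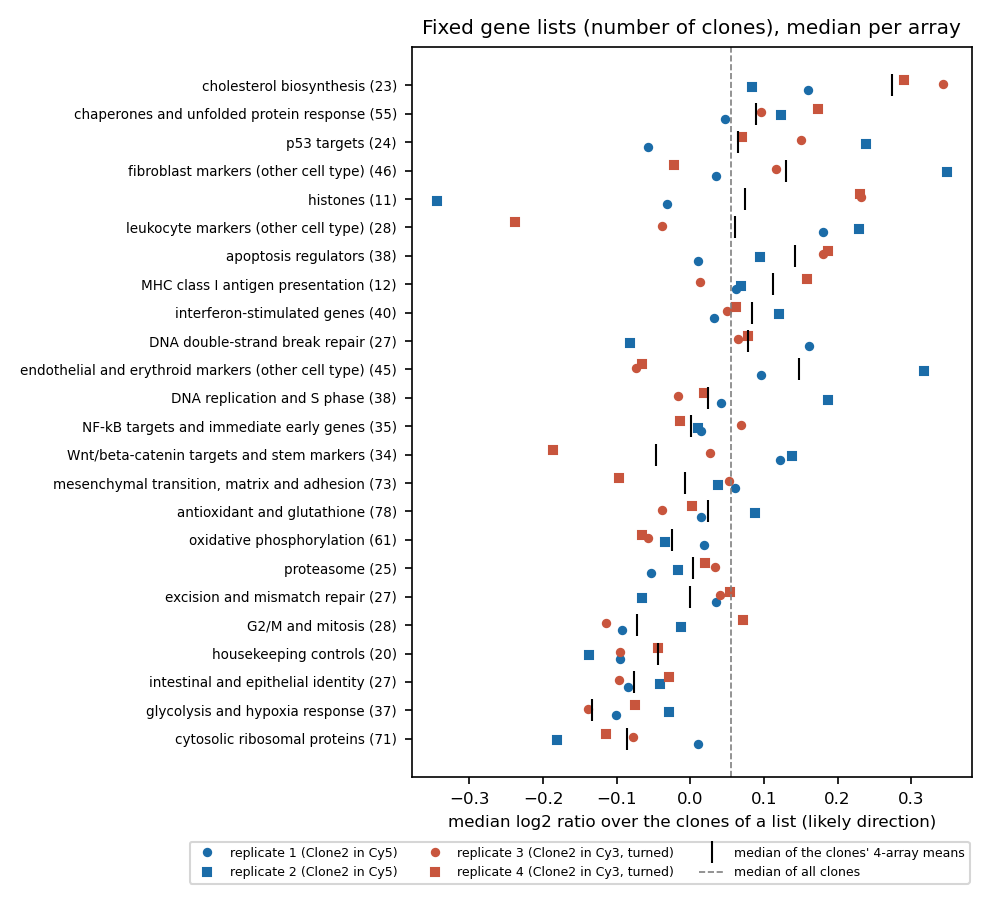
Median log2 ratio (horizontal axis) over the clones of each of the 24 gene lists on each array. Colour gives the dye orientation, blue for replicates 1 and 2 and red for replicates 3 and 4. Circles mark replicates 1 and 3, and squares replicates 2 and 4. A vertical tick marks the median of the clones' means and a dashed line the median of all clones at 0.06. The number of clones is in brackets. Cytosolic ribosomal proteins lie between -0.18 and 0.01 and cholesterol biosynthesis between 0.08 and 0.34.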

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

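The tests of neighbouring spots and of other clones were set before their results were seen, and the comparison with the share expected from signs alone was chosen afterwards. Of 49 sets of 4 array values, 7 had an array standing apart from the others, where chance gives about 1 in 20, or 2.45. That chance count does not hold for 4 of the 7, which are clones chosen for large means, since a large mean favours a single extreme array. Nor does it hold for the flagged sub-array, which was picked for its wide spread on replicate 4. In the sub-array of row 9 and column 1, the SD of the ratios was 2.58 on replicate 4 and 0.556 to 0.785 on the others. On replicate 4 also stood apart TMEM107 at 5.38 (others 1.46 to 1.64), SOX10 at 4.58 (1.17 to 1.68), HNMT at 7.35 (0.18 to 0.65) and CORIN at 7.02 (0.26 to 0.37). Adjacent spots in the wide sub-arrays had rank correlations of 0.142, 0.0723, 0.186 and 0.522 on replicates 1 to 4, and 0.0758, 0.0891, 0.109 and 0.0957 in the other sub-arrays. The median of the excision and mismatch repair genes was -0.065 on replicate 2 and 0.03 to 0.05 on the others. The median of the mesenchymal and matrix genes was -0.10 on replicate 4 and 0.04 to 0.06 on the others.

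With replicates 3 and 4 turned, 132 of 189 clones at 2-fold lay in the sub-arrays with a wide spread on replicate 4. These included the 10 largest. Unturned, 119 of 197 lay outside them. Those sub-arrays hold 14.5% of all clones, so even unturned they held more than their share of the clones at 2-fold. A spatial artefact of the slide or print is a candidate explanation: adjacent spots there, which hold different genes, had a rank correlation of 0.427 in their mean ratio, highest on replicate 4, above all 1000 shuffles of positions (highest 0.0529, p = 0.001, the smallest they can give), against 0.127 in the other sub-arrays, where it also exceeded all 200 shuffles (highest 0.0152, p = 0.005, the smallest they can give). An expression difference between irradiated Clone2 and Clone10 predicts that other clones of the same genes elsewhere share the sign, and 31 of 49 did (63.3%, exact 95% interval 48.3% to 76.6%, one-sided exact binomial p = 0.0427 against an even split). An even split was the wrong reference, since 57.3% of clones outside were positive. Against the 54.6% expected from signs alone, a reference chosen after the result was seen, the same binomial test gave p = 0.141. The 49 clones were set against only 34 clones at 2-fold, so they are not all independent. The interval may be too narrow and both p-values too small. The median log2 ratio of the 49 clones was 0.07, against 0.05 over all clones outside the wide sub-arrays. That median was not aligned to the signs of the clones at 2-fold. An expression difference therefore stays open, and any weak spots left in the table were not tested.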

How the results depend on the processing

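Settings with wide sub-arrays left out, with sub-arrays centred and scaled, with replicates 1 and 2 only, and the unturned 2-fold counts and gene lists were chosen after the result was seen. Under all 17 alternatives of the gene test 0 clones passed in limma, with smallest adjusted p between 0.0814 (without replicate 3) and 1 (minimum fold change of 1.5), and 108 to 1862 clones at an unadjusted p under 0.05. The dye effect gave 0 wherever it was fitted. The 2-fold positive clones, 167 in all, numbered 255 to 360 with an array left out, where agreement of fewer arrays is needed, 50 with the wide sub-arrays left out and 61 with sub-arrays scaled. The 22 negative ones numbered 31 to 92, 7 with the wide sub-arrays left out, and 45 with replicates 3 and 4 unturned. The ribosomal protein list stayed below the other clones in camera throughout, though its own median was 0.01 unturned, with an adjusted p of 0.623 with an estimated correlation, 0.188 with fry, which tests it against no change, 0.0636 with 1 value per gene, 0.693 unturned and 0.157 with the wide sub-arrays left out. It ranged from 0.0140 to 0.30 with an array left out, and the cause was not tested. It passed with no dye coefficient, arrays centred, arrays at the same spread, without replicate 1 and with sub-arrays scaled. No other list passed in these settings. Of 312 list values 27 took the other direction, and of 228 values of named clones 17, 11 of each with replicates 3 and 4 unturned, and 0 of those with the other direction passed. A fit needing values on at least 3 arrays was not run because 0 cells were missing, and duplicateCorrelation was not run because nearly all clones had 1 spot. Each ratio already pairs both RNAs within an array, and no further pairing was possible because all arrays form a single group. Signal over background was not analysed here, so a limit from weak spots is unknown.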

Other observations

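The tests of clone agreement, of turning and of sign patterns were chosen after the results were seen. Clones of the same gene, 2246 pairs, had a Spearman correlation of 0.0583 in their mean ratio (Pearson 0.0529), and Spearman was chosen after a first look at Pearson values. Spots of the same clone on an array, 279 pairs, had Pearson correlations of 0.0744, 0.266, 0.193 and 0.187 on replicates 1 to 4. Against pairs of different genes from the same sub-arrays, p was 0.002, but 1 of 1000 draws reached 0.0778, and the criterion set for excluding shared position asked that all draws be exceeded, so shared position stays open as an explanation. If the ratios of replicates 3 and 4 had been turned before deposit, the unturned means would agree better. Turned minus unturned, the difference was 0.0154 (bootstrap 95% interval -0.0462 to 0.0733), so the direction cannot be told apart by this test.

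The count of clones at an unadjusted p under 0.05, without the dye coefficient, was 1018 for the signs of the dye labels. Of the 8 possible sign patterns of the 4 arrays, 2 gave as many, this one included, and the other, with no array turned, gave 1584. With 8 patterns no share under 0.05 can be reached. The same unturned pattern gave 3776 clones of the same sign on all 4 arrays, against 3001 when turned, and 119 clones at 2-fold outside the wide sub-arrays, against 57. A pattern with only replicate 3 turned, which matches neither orientation, gave 120, so that count does not bear on the direction. With the dye coefficient, 1704 clones stood at an unadjusted p under 0.05 unturned and 1275 turned, and 3 of 4 correlations between orientations were positive as deposited. The same-sign and unadjusted counts and the correlations lean against the turned direction, and a gene-specific dye effect or ratios turned before deposit could each give them, which the difference of 0.0154 between turned and unturned clone agreement does not settle.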
